A study of Mus musculus with 5 samples.

How the data were processed

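RNA of sorted CD4SP thymocytes was extracted with TRIzol and column purification, amplified with the Ambion WT Expression Kit and labelled with biotin, per the labels' protocols. Each of the 5 samples, 2 wild type and 3 PLZF transgenic, was hybridised to an Affymetrix mouse exon array. The submitters' processing notes name RMA, Affymetrix Expression Console and the mm9 build, and their versions are not given in the sources used here. The deposited table holds intensity values on a linear scale, 1 column per array. The log2 of 100.0% of the values fell within 0.001 of a unit of the 5th decimal, which is what values on a log2 scale with 5 decimals give once the log is undone. In its standard form, RMA summarises the probes of a transcript by median polish after quantile normalization of the arrays, which makes the arrays' distributions alike and can hide a shift shared by most genes.

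The table used here has 65529 rows in ascending order of identifier, of which 14011 were paired with 1 gene symbol, 864 with several and 50654 with none in the platform annotation given with the data. Of the rows with 1 symbol, the Entrez identifiers of 13715 matched the mouse reference table (GRCm38.p6), and 0 symbols needed an update. That assembly differs from mm9, so no coordinates are printed, and it served only for names and for the share of genes covered per chromosome. Genes without such a row, Zbtb16 among them, were not analysed here.

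The planned test assumed log2 values. Since the values were linear, log2(intensity + 1) was used, the fallback set before the data were examined. For the 1257 genes with several rows the row with the highest mean over all arrays was kept, which gave 12267 genes, with no filter on level. Transgenic minus wild type was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 with 3 residual degrees of freedom, and p values were adjusted by Benjamini and Hochberg over all genes. The threshold was an adjusted p of 0.05. The prior degrees of freedom that limma estimated were 0.5, so the moderation of the variances was weak. An exact permutation test of 2 arrays against 3 cannot give a p below 0.1 and was not used. Log2 changes are given with the SE of the fit, and group means with the SD over arrays.

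Before the data were examined, 25 gene lists were fixed, covering T cell states, lineage, signalling, metabolism and markers of cell types outside the sort. The 23 lists with at least 5 measured members were tested with limma's camera, two-sided, with a preset correlation between genes of 0.01, beside camera with an estimated correlation and the rotation test fry. None of the 5 lists past the preset test stayed under the threshold with an estimated correlation. For the T cell receptor signalling and CD4 helper lists that estimate was -0.0125 and -0.0551, below the preset. A higher correlation was thus not what removed these lists. Their unadjusted camera p values with the estimate were 0.00898 and 0.0751. Genes were named by a rule set at the same time. It took Zbtb16, the 12 largest rises and 12 largest falls past the threshold with no overlap between groups, and per list up to 4 members past the threshold or, failing that, the member with the largest change. Under that rule, symbols of predicted genes, non-coding RNAs and olfactory or vomeronasal receptors were counted but not named among the largest changes, and 13 higher and 14 lower genes were of this kind. The exceptions are said where they occur to have been chosen after their values were seen.

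Alternatives planned before the data were examined were the replicate number as a block, an intensity trend with a robust fit, median centring, cyclic loess and quantile normalization between arrays, the mean of a gene's rows, a filter on dim genes, array weights, each array left out in turn, other thresholds, and all rows of the table. Chosen after seeing the data were log2 without a pseudocount, and the 4027 genes with 5 different values, with all arrays and with each left out. Values were called identical where they differed by at most 0.000005 on the log2 scale. Where an array is left out of the wild type pair, the lone array is assumed to vary like the transgenic ones. The procedure was tested on simulated data made from the means and residual SDs of the 12267 genes. It recovered 80 of 100 genes changed by 1 and 95 of 100 changed by 2 on the log2 scale, and called 16 of 12067 unchanged genes. A simulated list of 20 genes shifted by 0.5 had a camera p of 1.44e-31, and an unchanged list of 0.849. Made from means and SDs alone, the simulated genes are not correlated with each other. The estimate for the proliferation list was 0.578, so the simulation does not check camera on correlated lists. Nor does it keep identical values in only some arrays of a gene. In the data 67.2% of the genes had identical values in several arrays, so the recovery and false calls of such genes are not checked.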

Results

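Thymocytes that carry CD4 but not CD8, called CD4 single-positive (CD4SP) cells, were isolated by flow cytometry from C57BL/6J mice aged 4 to 6 weeks and profiled on Affymetrix mouse exon arrays. The series held 2 arrays from wild type mice and 3 from mice carrying a transgene for PLZF, a zinc finger transcription factor that directs the development of innate-like T cells such as NKT cells. The labels call the samples biological replicates and describe each as cells from pooled mice. The comparison asks which transcripts differ between CD4SP cells of the 2 genotypes. The median intensity per array lay between 59.0 and 60.3, and the highest intensity between 13300 and 14527. Across genes, which are not independent replicates, log2 values of the 2 wild type arrays correlated at r = 0.996 and those of each pair of transgenic arrays at r = 0.998, against 0.990 to 0.991 between genotypes. The number of arrays limits the precision of every value. A gene was represented for 80.0% of the protein-coding genes of chromosomes 1 to 3 and 10 to 19, 35.6% of those of chromosome 4, and 1.0% of those of chromosomes 5 to 9, X and Y in GRCm38.p6. Zbtb16, the gene that encodes PLZF, was not analysed here, so its level gives no check of the genotype labels. Cd4, Cd8a and Foxp3 were also not analysed here.

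CD4SP cells of PLZF transgenic mice had more transcript for Cysltr2, Il18r1, Rarg and Il2ra, and less for Rflnb and for most measured genes of naive T cells. The largest rise among the genes named by rule was that of Cysltr2, a receptor for cysteinyl leukotrienes. Its log2 intensity went from 5.54 ± 0.0004 (SD, n = 2) in wild type to between 9.97 and 10.03 in the 3 transgenic arrays. The change was 4.46 ± 0.02 (SE) or 22.1-fold (limma, Benjamini-Hochberg adjusted p = 3.30e-04). Il18r1, the ligand-binding chain of the interleukin-18 receptor, rose 8.81-fold and Rarg, a nuclear receptor for retinoic acid, rose 8.36-fold (limma adjusted p = 0.00699 and 0.00812). The largest fall among the genes named by rule was that of Rflnb, which encodes an actin regulator that binds filamin. It went from 10.09 ± 0.13 (SD, n = 2) to 6.74 ± 0.09 (SD, n = 3), or 10.2-fold (limma adjusted p = 0.00699). Bach2, a transcriptional repressor that restrains effector differentiation of T cells, was 4.73-fold lower in transgenic cells, at 9.11 ± 0.07 (SD, n = 3) against 11.35 ± 0.05 (SD, n = 2), with a limma adjusted p of 0.00699.

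Among 12267 genes tested, 211 were higher and 370 lower in transgenic cells at an adjusted p under 0.05 (limma, Benjamini-Hochberg), and 42 and 66 of these changed by at least 1 on the log2 scale. In all 581 the 3 transgenic arrays lay on the same side of both wild type arrays, a separation seen in 27.7% of all genes. Among the 4027 genes with 5 different values it was seen in 63.1%, against 20% by chance. The share of higher genes among those called was 36.3% on the values as deposited, 46.6% after cyclic loess and 51.1% after quantile normalization of the arrays. Only genes past the threshold that the naming rule admits are ranked here. After Cysltr2, Il18r1 and Rarg, the next largest rises among them were those of Fam124b (log2 change 2.50) and Qpct (2.34), which encodes glutaminyl cyclase. Lmo4 (2.15), a LIM domain transcription cofactor, and Il2ra (2.13) came next. They were followed by Eya2 (1.73), a transcriptional coactivator with phosphatase activity, Sytl3 (1.71), Ly96 (1.70), the co-receptor of TLR4, Npas2 (1.60), a transcription factor of the circadian clock, and Il17rb (1.58). Their standard errors lay between 0.08 and 0.28, and their limma adjusted p values between 0.00867 for Lmo4 and 0.0476 for Qpct. After Rflnb, the largest falls were those of Cd200r1 (log2 change -2.73), an inhibitory receptor for CD200, Neurl3 (-2.35), Calhm6 (-2.34), AI504432 (-2.29), Ppp3cc (-2.28), a catalytic subunit of calcineurin, and Igfbp4 (-2.25). Bach2 (-2.24), Ptgfrn (-2.10), Dapl1 (-2.02), Gpr183 (-1.98), an oxysterol receptor that guides lymphocyte migration, and Slc16a5 (-1.87), of the monocarboxylate transporter family, completed the 12 largest falls. The wild type mean of Cysltr2 and the transgenic means of Cd200r1 and Calhm6 lay below 5.63, the 25th percentile of gene means, where array background can compress a fold change.

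**Figure D1:**
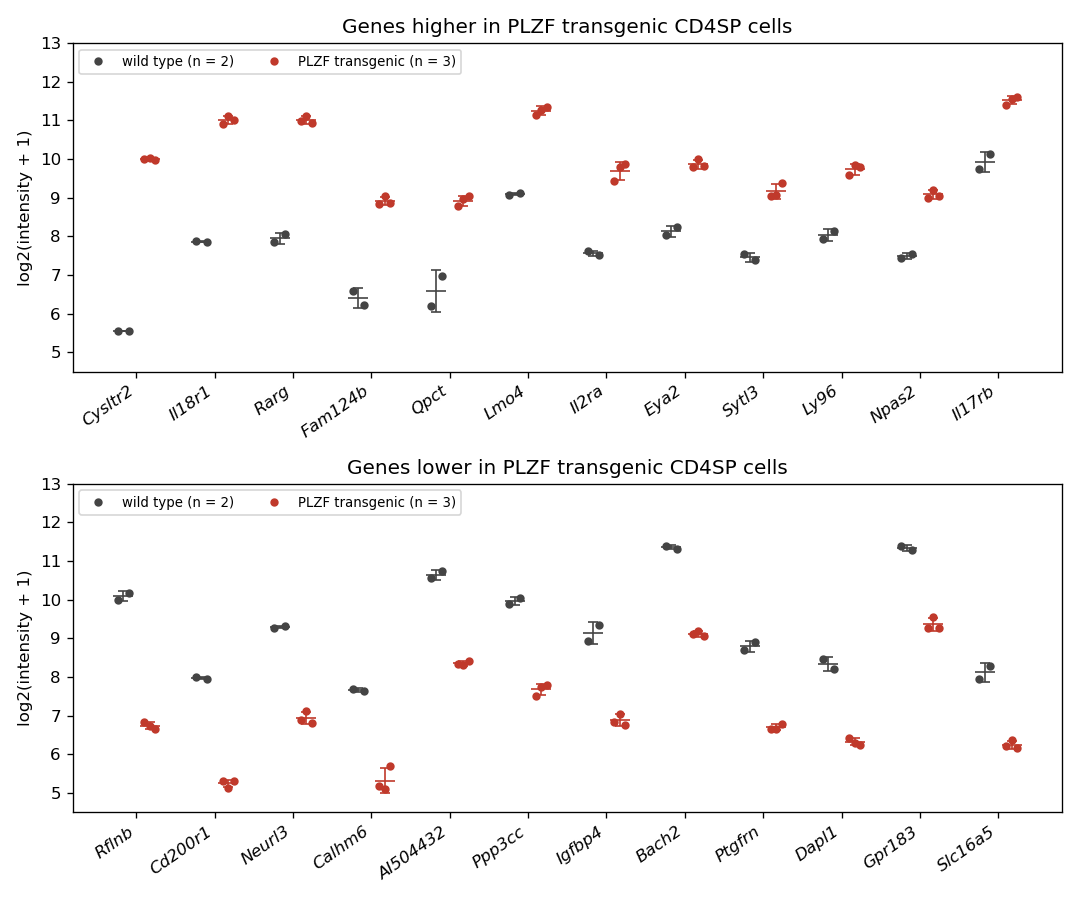
Log2(intensity + 1) on the vertical axis for the 12 genes with the largest rise (upper panel) and the 12 with the largest fall (lower panel). Only genes past the threshold, with no overlap between groups and a symbol type that the naming rule admits, were ranked. Each array is a point (dark, wild type, n = 2, and red, PLZF transgenic, n = 3), with the mean and SD as horizontal bars with whiskers. All transgenic points of each gene lie on one side of both wild type points, from Cysltr2 (a log2 change of 4.46) to Slc16a5 (-1.87).

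The number of genes called moved with the arrays used. It was 4, 45 and 10 without PLZF transgenic replicate 1, 2 and 3. Among the 4027 genes with 5 different values, a set chosen after seeing the data, it was 547, 513 and 553. The sizes of the largest changes moved less. With 1 array left out in turn, the log2 change of Cysltr2 ran from 4.45 to 4.48 and that of Il18r1 from 3.09 to 3.19. Bach2 ran from -2.28 to -2.21 and Rflnb from -3.43 to -3.26, while Qpct moved more (1.95 to 2.73). Of the 51 genes named by rule that passed the threshold, 50, 45 and 50 were no longer past the threshold without transgenic replicate 1, 2 and 3, and 6 and 14 without wild type replicate 1 and 2. Calhm6, Fasl, Cd83, Gbp2, Gbp3 and Cd74 passed in none of these 5 fits. With an intensity trend and robust fit, Qpct, Cd83, Cd200, Egr1, Gbp3, Gbp2, Cd74 and Cd5 had adjusted p values between 0.0508 and 0.0640, and with array weights 50 of the 51 genes did not pass. Member counts of the gene lists moved in the same way. Of the 266 list genes measured, 45 passed with all arrays, and 0, 5 and 2 without transgenic replicate 1, 2 and 3. Member counts from fits with a lone wild type array are not read, since these fits called many genes with identical values in the transgenic arrays.

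Genes of naive T cells and of T cell recirculation fell together. Of 17 measured members of this list, 11 fell and 1 rose at an adjusted p under 0.05 over all genes tested, and 15 fell and 1 rose when adjusted over the list alone. Without transgenic replicate 1, 2 and 3 there were 0, 1 and 2 that fell, with array weights 0, and 14 after median centring, cyclic loess or quantile normalization. The mean log2 change was -0.86 ± 0.79 (SD over the members), and -0.88 to -0.84 with 1 array left out in turn. Besides Igfbp4, Bach2 and Dapl1, S1pr1, the sphingosine 1-phosphate receptor through which thymocytes leave the thymus, was 3.43-fold lower, at 10.45 ± 0.15 (SD, n = 3) against 12.22 ± 0.03 (SD, n = 2), with a limma adjusted p of 0.0165. Named after their values were seen, Bcl2, which encodes an inhibitor of apoptosis (log2 change -1.37), Id3 (-0.89), Lef1 (-0.60) and Sox4 (-0.59) also fell, and Il7r, the interleukin-7 receptor alpha chain, was the member that rose (0.31, limma adjusted p = 0.0291). The list was shifted downward against the other genes in limma's camera test (adjusted p = 1.80e-12 over the 23 lists tested, adjusted p = 0.179 with an estimated correlation).

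Several genes induced directly by T cell receptor signalling were also lower. Of 17 measured, 6 fell and none rose over all genes tested, and 9 fell when adjusted over the list alone, with a mean log2 change of -0.34 ± 0.36 (SD over the members). The zinc finger transcription factors Egr2 (-1.03 ± 0.04, SE) and Egr1 (-0.73 ± 0.09) and the nuclear receptors Nr4a3 (-0.73 ± 0.06) and Nr4a1 (-0.66 ± 0.04) changed most, with limma adjusted p values of 0.00957, 0.0460, 0.0233 and 0.0170. No member of this list passed without transgenic replicate 1, 2 or 3 or with array weights. With 1 array left out in turn, the mean log2 change ran from -0.36 to -0.33. Camera gave an adjusted p of 2.05e-07, and adjusted p = 0.179 with an estimated correlation. In the list of immediate early and dissociation stress genes, 0 of 10 measured members passed over all genes tested, while 1 rose and 3 fell when adjusted over the list alone. Hspa1a, a stress-induced chaperone, had the largest change of that list (-0.59 ± 0.11, SE, limma adjusted p = 0.0940).

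Cytokine and chemokine receptors of effector T cells moved both ways. Of 25 listed, 8 were measured, and of these 3 rose and 1 fell over all genes tested. When adjusted over the list alone, 4 rose and 1 fell. Il18r1 (log2 change 3.14 ± 0.07, SE), Il2ra (2.13 ± 0.17), which encodes CD25, and Il17rb (1.58 ± 0.15), a subunit of the interleukin-25 receptor, rose. Ifngr1, the ligand-binding chain of the interferon gamma receptor, fell by 1.26 ± 0.13 (limma adjusted p = 0.0350). The partner chain of Il18r1, Il18rap, chosen after its value was seen, had a change of 3.20 ± 0.43 (SE) with a limma adjusted p of 0.0573 and a wild type SD of 0.88. The mean change of the list was 1.09 ± 1.66 (SD over the members), with a camera adjusted p of 0.0765 over all genes and of 0.0161 over the genes with 5 different values, a set chosen after seeing the data. It was 0.124 after cyclic loess and 0.194 after quantile normalization, and over all genes the list had an adjusted p = 0.456 with an estimated correlation. Il2ra was also the member that passed among 4 measured regulatory T cell genes, over all genes tested and when adjusted over the list alone, and that list was too short to test. Without wild type replicate 2, Il2ra had a limma adjusted p of 0.0541, and without transgenic replicate 1, 2 or 3 of 0.0524, 0.118 and 0.120, in a range from 0.00134 to 0.307 over all settings.

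Transcription factors of effector and innate-like T cells showed no common direction. Over all genes tested, 2 of 16 measured rose and 3 fell, and 5 rose and 6 fell when adjusted over the list alone (camera adjusted p = 0.525). Id2, an inhibitor of E protein transcription factors, was 1.99-fold higher (limma adjusted p = 0.00867) and Ahr, the aryl hydrocarbon receptor, 1.34-fold higher (0.0236), whereas Egr2 was 2.04-fold and Hivep3 1.46-fold lower (limma adjusted p = 0.00957 and 0.0278). Gata3, chosen after its value was seen, had a log2 change of 0.05 (limma adjusted p = 0.458).

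Most cytokine genes did not pass the test, and most lay below the median of gene means, 6.93, where a change is harder to see. The mean of the list was 6.03 to 6.11 per array. Only 6 members passed the dim filter, and in the fit with that filter 3 rose and 1 fell. Of 23 cytokine and chemokine genes measured, Lta, which encodes lymphotoxin alpha, rose (0.73 ± 0.05, SE, limma adjusted p = 0.0210) and Tnfsf11, which encodes RANKL, fell (-1.33 ± 0.08, 0.0157). When adjusted over the list alone, 3 rose and 1 fell (camera adjusted p = 0.200). Of 25 natural killer receptor and cytotoxic genes listed, 10 were measured. The Klr genes and Ncr1 were not analysed here, so the list does not speak for these receptors. Fasl, the ligand of the death receptor Fas, rose 2.75-fold (limma adjusted p = 0.0347) and none fell over all genes tested. When adjusted over the list alone, 1 rose and 2 fell. The same counts came over all genes after median centring, cyclic loess or quantile normalization. The mean change of these 10 was -0.03 and the median 0.0069, opposite in sign (camera adjusted p = 0.861). With 1 array left out in turn, the mean ran from -0.11 to 0.06.

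Activation and costimulatory genes divided, with 3 of 14 measured higher and 5 lower, both over all genes tested and when adjusted over the list alone. Slamf6 (1.29 ± 0.13, SE), a homotypic receptor of the SLAM family, and Cd83 (1.06 ± 0.13) rose, and Cd200 (-0.52 ± 0.06) and Slamf1 (-0.37 ± 0.02) fell, with limma adjusted p values of 0.0339, 0.0473, 0.0469 and 0.0146. The mean change was 0.04, while the median was -0.10 and camera's direction downward (adjusted p = 0.0987, and 0.0478 after quantile normalization). Camera with an estimated correlation gave an adjusted p of 0.456. With 1 array left out in turn, the mean ran from 0.01 to 0.07. Of 17 adhesion and integrin genes, 2 fell and none rose over all genes tested, and 1 rose and 6 fell when adjusted over the list alone (camera adjusted p = 0.0765). Cd2, an adhesion receptor that aids T cell activation, fell by 1.11 ± 0.04 (SE) and Icam2 by 0.23 ± 0.02 on the log2 scale (limma adjusted p = 0.00955 and 0.0338).

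Proliferation genes had lower values as a list, with a single member past the test over all genes. Of 21 measured, Ube2c, a ubiquitin-conjugating enzyme of mitosis, fell by 0.50 ± 0.05 (SE, limma adjusted p = 0.0315), and 1 rose and 8 fell when adjusted over the list alone. The mean of the list was 8.41 and 8.60 in the wild type arrays and 8.05, 8.13 and 8.21 in the transgenic arrays, a mean change of -0.37 ± 0.27 (SD over the members). Over all genes tested, 1 rose and 5 fell after cyclic loess or quantile normalization, and 1 rose and 10 fell among the 18 members with 5 different values, a set chosen after seeing the data. Without transgenic replicate 1, 2 or 3 no member passed. The mean change ran from -0.47 to -0.28 with 1 array left out in turn. Camera gave an adjusted p of 5.15e-06, and adjusted p = 0.456 with an estimated correlation. None of 9 cholesterol synthesis genes passed over all genes tested and 3 fell when adjusted over the list alone, and Idi1 had the largest change (-0.38 ± 0.08, SE, limma adjusted p = 0.125). Their mean change of -0.17 ± 0.15 (SD over the members) gave a camera adjusted p of 0.00942, adjusted p = 0.456 with an estimated correlation, and 0.196 without wild type replicate 2. Neither the 9 glycolysis genes nor the 15 autophagy and lysosome genes had a member past the test over all genes or when adjusted over the list alone. Their members with the largest changes were Pfkp (0.23 ± 0.10, SE) and Ctsl (-0.27 ± 0.11), and the camera adjusted p values were 0.918 and 0.983. With 1 array left out in turn, Pfkp ran from 0.09 to 0.36 and Ctsl from -0.43 to -0.11. The autophagy list had a mean change of -0.02 and a camera direction upward. Over all genes, 1 autophagy gene rose after cyclic loess, 2 after quantile normalization and 2 with the dim filter, and none fell. Of 14 interferon-stimulated genes, the guanylate-binding protein genes Gbp3 (0.83 ± 0.10, SE, limma adjusted p = 0.0479) and Gbp2 (0.74 ± 0.08, 0.0371) rose and none fell, over all genes tested and when adjusted over the list alone (camera adjusted p = 0.293). Neither Gbp2 nor Gbp3 passed without any 1 of the 5 arrays, or with a trend and robust fit (limma adjusted p = 0.0508 and 0.0640). The calls in the interferon-stimulated, glycolysis and autophagy lists depended on the wild type array kept. Fits with a lone wild type array called many genes with identical values in the transgenic arrays, so their counts are not read here. With 1 array left out in turn, the interferon-stimulated list had a mean log2 change of 0.04 to 0.24. The range was -0.06 to 0.06 for glycolysis and -0.04 to 0.0008 for autophagy.

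Of 15 listed genes of the CD4 helper lineage, 5 were measured. Of these, 3 fell over all genes tested and when adjusted over the list alone. They were St6gal1, a sialyltransferase (-0.82 ± 0.04, SE), Cd5, an inhibitory co-receptor (-0.36 ± 0.04), and Zbtb7b, which encodes the lineage factor ThPOK (-0.13 ± 0.01), with limma adjusted p values of 0.0140, 0.0437 and 0.0269. Zbtb7b had an adjusted p of 0.0711 after median centring, 0.0719 after cyclic loess and 0.165 after quantile normalization. The list's mean change was -0.25 ± 0.36 (SD over the members), with a camera adjusted p of 0.0397, adjusted p = 0.456 with an estimated correlation, and 0.311 and 0.332 without wild type replicate 1 and 2. Of 7 CD8 single-positive T cell genes, Dapl1, which the naive list also holds, fell over all genes tested. When adjusted over the list alone, 2 rose and 5 fell (camera adjusted p = 0.0765). Over all genes, 1 rose and 3 fell after median centring, cyclic loess or quantile normalization. None of 10 immature double-positive thymocyte genes passed over all genes or when adjusted over the list alone, and Dntt, the terminal transferase of antigen receptor rearrangement, had a change of -0.54 ± 0.16 (SE, limma adjusted p = 0.244, list camera adjusted p = 0.505).

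Markers of cells outside the sorting gate moved in few cases. Among 6 dendritic cell and MHC class II markers, Cd74, the MHC class II invariant chain, rose (0.92 ± 0.10, SE, limma adjusted p = 0.0410), and 2 rose and none fell when adjusted over the list alone (camera adjusted p = 0.273). Cd74 did not pass without any 1 of the 5 arrays, or with a trend and robust fit (limma adjusted p = 0.0559). Prss16, a protease of thymic epithelium, fell by 0.28 ± 0.01 (limma adjusted p = 0.0103) as the 1 member of 14 thymic epithelial and stromal markers past the test, over all genes and when adjusted over the list alone (camera adjusted p = 0.653). Car2, a carbonic anhydrase, fell by 0.43 ± 0.04 (limma adjusted p = 0.0287) among the 6 measured of 20 erythroid and platelet markers. No globin gene was among these 6, and 2 fell when adjusted over the list alone (camera adjusted p = 0.273). Neither Prss16 nor Car2 passed without transgenic replicate 1, 2 or 3. No member passed, over all genes or when adjusted over the list alone, among 11 B cell markers, 8 macrophage and monocyte markers, 11 neutrophil and mast cell markers and 2 gamma delta T cell genes. The largest changes there were those of Fcrla (-0.31 ± 0.09, SE), Mpeg1 (-0.67 ± 0.30), S100a9 (0.36 ± 0.37) and Blk (0.03 ± 0.02), and the camera adjusted p values of the first 3 lists were 0.505, 0.379 and 0.293. Mpeg1, a macrophage gene, was at 6.97 and 7.81 in the wild type arrays. Calls in these marker lists also changed with the wild type array kept, with the same limit on the counts. With 1 array left out in turn, the mean log2 change ran from -0.015 to 0.036 for B cell and -0.28 to -0.12 for macrophage markers. It ran from 0.03 to 0.14 for neutrophil and 0.18 to 0.24 for dendritic cell and MHC class II markers. For thymic stromal markers it ran from -0.045 to -0.034, and for erythroid markers from -0.25 to -0.14.

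**Figure D2:**
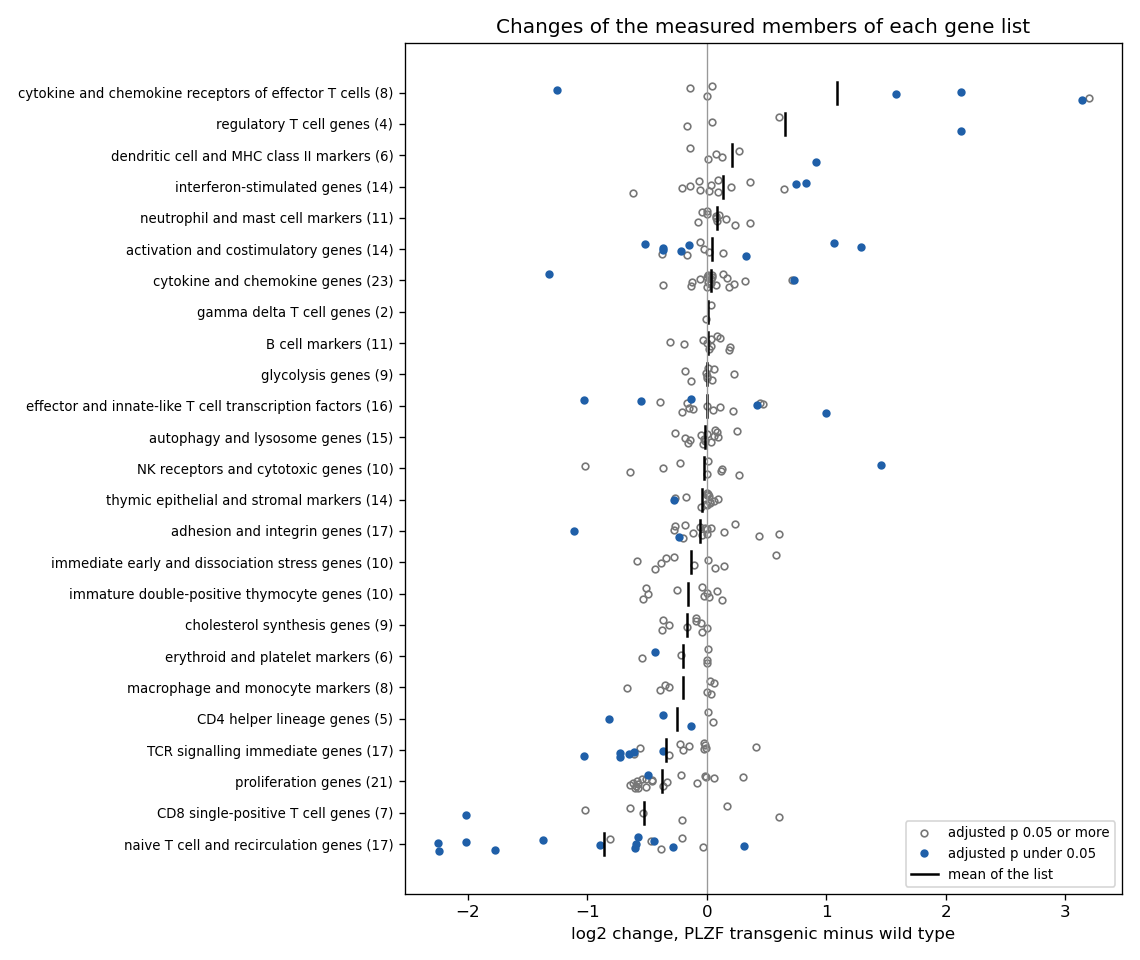
Log2 change (PLZF transgenic minus wild type) on the horizontal axis for each measured member of the 25 gene lists, with the number of measured members in brackets. Filled points are members with a limma adjusted p under 0.05, open points the others, and vertical bars the list means, which run from -0.86 for naive T cell and recirculation genes to 1.09 for cytokine and chemokine receptors of effector T cells.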

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

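Rows of the table without a single gene name lie outside the comparison of genes, and they carried signal that differed between genotypes. In a limma fit over these 51518 rows, 15 were higher and 43 lower in transgenic cells at a Benjamini-Hochberg adjusted p under 0.05, and all of them changed by at least 1 on the log2 scale. At an unadjusted p under 0.05 there were 6108. The largest rises were those of row 6763567, from 4.90 ± 0.07 (SD, n = 2) to 11.54 ± 0.05 (SD, n = 3) on the log2 scale (limma adjusted p = 9.04e-04), and row 6865890, with a change of 4.89 ± 0.23 (SE, limma adjusted p = 0.0219). The largest falls were those of rows 6754684 (-5.57 ± 0.29, SE, limma adjusted p = 0.0260) and 6754683 (-4.99 ± 0.22, 0.0185). In 3 of these 4 the lower group mean lay below 5.63, the 25th percentile of gene means, where array background can compress a change. Their genes were not analysed here. A group of 2 and a group of 3 arrays are too small for a test of single arrays that stand apart.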

How the results depend on the processing

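All 581 genes called kept their sign after median centring, cyclic loess and quantile normalization, and 577 did with the mean of a gene's rows. The other fits could not turn a sign, since the groups do not overlap in any of these genes. The count of genes called stayed within 1.5 times of 581 with a trend and robust fit (411), median centring (758), the mean of rows (557) and log2 without a pseudocount (579). It was 1089 after cyclic loess, 1130 after quantile normalization, 941 of 6134 genes above the dim filter, and 1 (Cysltr2) with array weights, where 1010 genes had an unadjusted limma p under 0.05. With a change of at least 1 it was 108, at an adjusted p under 0.1 it was 1031, and over all rows 202. Without 1 array it ranged from 4 (without transgenic replicate 1) to 2890 (without wild type replicate 1), with 45 and 10 without transgenic replicate 2 and 3 and 1852 without wild type replicate 2. Of the 2890 and 1852 genes, 1333 and 883 had identical values in the transgenic arrays. Among the 4027 genes with 5 different values, a set chosen after seeing the data, it was 1043, of which 481 were among the 581, and between 513 and 1058 without each array in turn. The cause of the other differences was not tested.

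With the replicate block over replicates 1 and 2 of both genotypes, limma called 0 genes, with 1917 at an unadjusted p under 0.05, and 4 lists. The labels do not say what a number shares, so the main fit does not pair samples by number. Across genes the differences of the 2 pairs correlated at 0.109, which cannot decide whether samples of 1 number share a day or batch.

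Of the 23 gene lists, 5 were shifted in camera and between 4 and 7 under the other alternatives that tested all 23 with the preset correlation, with 4 to 5 without 1 array. It was 4 of the 16 lists tested with the dim filter and 4 of the 12 tested over genes with 5 different values. With an estimated correlation there were 0, and with fry, which does not set a list against other genes, 13. The CD8 single-positive list passed after median centring, cyclic loess and quantile normalization, and with array weights (adjusted p = 0.0259, 0.0254, 0.0175 and 0.0405, in a range of camera values from 0.0175 to 0.456). The effector receptor list passed after median centring (0.0479), with the dim filter (0.0144) and over genes with 5 different values, with all arrays (0.0161) and without each in turn (0.00542 to 0.0236), and not after cyclic loess (0.124) or quantile normalization (0.194), in a range of camera values from 0.00542 to 0.456. The activation list passed after quantile normalization (0.0478) and the adhesion list with array weights (0.0424). Among the camera settings, the interferon-stimulated and glycolysis lists passed only without wild type replicate 2, with mean log2 changes of 0.24 and 0.06. That fit rests on a lone wild type array and called many genes with identical values in the transgenic arrays. No alternatives were run for Zbtb16, which was not analysed here. Dim genes are limited by signal over background.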

Other observations

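The lists described here, and the tests of the stage shift and of regulatory T cells, were chosen after the results of the comparison were seen, and the tests on identical values before their outcome was seen. Of 12 measured circadian clock genes, a list prompted by Npas2, 3 rose, Npas2 among them, 1 fell and 8 did not pass over all genes tested, with as many calls when adjusted over the list alone. Nr1d2, which encodes the clock repressor REV-ERB beta, rose by 1.37 ± 0.06 (SE, limma adjusted p = 0.00968) and Fbxl21 by 1.18 ± 0.14 (0.0439), and Csnk1e, a casein kinase, fell by 0.42 ± 0.02 (0.0109). Per1 (0.23) and Nr1d1 (0.04) were not past the threshold, and the list was not shifted (camera adjusted p = 0.275 over 9 lists). Among 13 retinoid receptor and metabolism genes, Rxra, the partner receptor of Rarg, rose by 0.43 ± 0.03 (limma adjusted p = 0.0207) together with Rarg, and none fell, over all genes and when adjusted over the list alone (camera adjusted p = 0.233). Of 10 receptors for lipid mediators, Cysltr2, Lpar6 (0.25) and Ptger4 (0.12) rose and S1pr1, Gpr183 and Gpr132 (-0.72) fell over all genes tested, and 3 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.824).

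The list of SLAM family and partner genes divided, with 2 of 12 measured higher and 5 lower over all genes tested. The counts were the same when adjusted over the list alone (camera adjusted p = 0.0569). Slamf6 and Cd84 (0.36 ± 0.03, SE) rose, whereas Slamf1, Cd48 (-0.42 ± 0.05), Cd2 and Fyn fell. Sh2d2a, a T cell adaptor counted in the list though not a SLAM adaptor, fell too. Il6st, which encodes the shared cytokine receptor chain gp130, fell by 1.86 ± 0.06 (SE, limma adjusted p = 0.00812), and Stat6 was the other of 13 genes of the gp130 and JAK-STAT list that changed over all genes, while 1 rose and 2 fell when adjusted over the list alone. That list had a mean change of -0.16, a median of 0.02 and a camera direction upward (adjusted p = 0.983). In the BCL2 family, Bcl2 and Mcl1 (-0.36 ± 0.03) fell and none of the other members of 11 passed over all genes, and 1 rose and 3 fell when adjusted over the list alone. The family's mean change was -0.08, its median 0.09 and its camera direction upward (adjusted p = 0.731). Of 14 NF-kappaB pathway genes, Nfkb2 (0.25 ± 0.03) rose and Malt1 (-0.63 ± 0.04) and Nfkbiz (-0.40 ± 0.05) fell, and 2 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.398).

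Many genes had identical values in several arrays, within 0.000005 on the log2 scale. This held for 8240 of the 12267 genes (67.2%), and 1455 of them were identical in all 5. If the median polish of RMA were the source, the tied pair would hold the gene's median array, and it did so in 99.2% of 2170 genes with exactly 2 tied arrays, against 50% by chance. A floor set on dim values is argued against, since the tied value was the lowest in 5.26% of 2588 genes with exactly 3 tied arrays. Ties may thus be a product of the summary step, and 56 of the 581 genes called had some, 13 of them in all transgenic arrays.

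The fall of naive T cell and recirculation genes, in 11 of 17 measured members, could come from a shift of the sorted cells along maturation, since semi-mature and mature single-positive thymocytes are both in the CD4SP gate. Of 5 semi-mature genes measured, 4 fell and none rose over all genes and when adjusted over the list alone (camera adjusted p = 0.00171, adjusted p = 0.439 with an estimated correlation), and of 7 mature genes S1pr1 fell and Il7r rose, and 4 fell and 2 rose when adjusted over the list alone (camera adjusted p = 0.233). Most of these genes belong to the naive or T cell receptor signalling lists, and outside them stood 1 semi-mature gene, Rag2 (log2 change 0.123), and 2 mature genes, Itgb7 (0.15) and Slfn2 (-0.0048), none past the threshold. That is too few to decide, so a stage shift stays open. A direct effect of the transgene, which the design names, stays open as well and was not tested.

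The 4.37-fold rise of Il2ra could come from more regulatory T cells among the sorted CD4SP cells, which the gate admits. More such cells would raise the other regulatory T cell genes too, and the 3 others measured had a median log2 change of 0.0458. They were Ikzf2 (-0.17 ± 0.06, SE, limma adjusted p = 0.364), Socs2 (0.05 ± 0.03, 0.458) and Itgae (0.61 ± 0.21, 0.297). They go both ways, and the sorted cells that are not regulatory T cells may express them as well, so these values do not settle the source, and Foxp3 was not analysed here. An effect of the transgene on Il2ra also stays open and was not tested.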
